A study of Mus musculus with 5 samples.

How the data were processed

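Mouse embryos of 5 stages, E3.5, E4.5, E4.75, E5.5 and E6.0 (E is embryonic day), were each compared with E2.5 embryos on 2-colour cDNA arrays. Per the labels' protocols, E2.5 embryos were flushed from the oviduct, E3.5 embryos from the uterus, and later embryos were dissected from it. RNA of pooled embryos was amplified by a PCR-based method before labelling, per the labels. Each stage had 3 pools per the protocols. The E2.5 pools held 106 embryos on average, the E3.5 pools 61, the E4.5 pools 47 and the E4.75 pools 28. The pools of E5.5 and E6.0 embryos were the smallest, with means of 17 and 19. The protocols list the third and last of the stages after E2.5 as 4.8 and 6.5 days, where the sample titles say E4.75 and E6.0; the titles were used. There is 1 column of values per stage, and whether it averages pools, arrays or dye swaps is not given in the sources used here.

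The deposited table holds 15247 rows and 5 columns of log ratios made by the authors, read here as log2 of the named stage over E2.5. The base is not stated per the labels; the range of values rules out base 10 in practice, natural logarithms were not excluded, and every fold below rests on base 2. The direction comes from the sample titles, which name each column as the ratio of its stage to E2.5; per the labels, the named stage was in Cy3 and E2.5 in Cy5. Background correction, normalization and filtering by the authors are not given in the sources used here. The column medians were -0.01 at E3.5, -0.03 at E4.5, 0.08 at E4.75, -0.04 at E5.5 and -0.01 at E6.0, so the deposited values were centred close to 0. No intensities were used here, so the signal behind each ratio is unknown, and the number of arrays limits the precision.

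Rows were named through the platform annotation in GEO, matched on the row identifier. It gave 1 symbol to 8077 rows and several to 369, and 6801 rows were unnamed. Of the rows with 1 symbol, 8058 matched a current gene through the Entrez identifier and the rest kept the annotation's name. Rows with 1 symbol were averaged per symbol, which gave 6422 symbols, 1313 of them with 2 or more rows. The counts use the 6407 symbols and 15217 rows with a value in all 5 columns. Because the names could not be taken as given, the agreement of rows that share a symbol was measured as the correlation over all pairs of such rows, and the names were shuffled 10000 times among the rows. This check of the names, and every row-level count, was chosen after the data had been seen. On simulated rows with a shared part that gives a correlation of 0.5, the same code returned 0.49.

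With 1 column per stage, no test and no replicate check was possible for a single stage or for a step between stages; symbols with a log2 ratio of at least 1 in either direction (2-fold) were counted. A linear trend on embryonic day over the 5 columns was fitted with limma 3.58.1 in R 4.3.3 (3 residual degrees of freedom, Benjamini-Hochberg adjusted p under 0.05). Its p-values measure only the deviation of these 5 columns from a line in day. Tested on simulated data for 6407 symbols, the trend step recovered 1 of 67 symbols given a slope of 0.5 per day, 35 of 67 at 1 per day and 60 of 66 at 2 per day, with 5 false calls. The simulated noise was independent between columns, whereas the real columns were correlated. The simulation therefore does not give the recovery or the false-call rate for these data. For 23 gene lists fixed before the data were examined, camera was run on the trend (preset correlation 0.01, and estimated), and each list's median at each stage was placed among 10000 random lists of the same size, matched on the number of rows per symbol. Python 3.11.15 with SciPy 1.17.1 did the rest.

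The symbols named were set by a rule fixed before the data were examined: the 5 highest and 5 lowest per stage, up to 10 rising and 10 falling past the trend threshold, up to 4 members per list with the largest ratio in either direction at E6.0, the 3 most raised and 3 most lowered per step, and 35 key genes where measured, of which 20 were. From these, the text gives the extremes, the trend calls and the key genes with several rows. The alternatives were other centring and scaling of the columns, a 3-fold threshold, the median over rows, symbols with 2 or more rows, leaving out each stage, the rank of the stage, a contrast of the later stages, robust variance moderation and another adjusted p. Rows in place of symbols were added after the data had been seen.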

Results

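The data were 5 columns of log2 ratios, 1 each for mouse embryos at E3.5, E4.5, E4.75, E5.5 and E6.0, each relative to E2.5. E2.5 embryos are in cleavage, E3.5 embryos are blastocysts, and the later stages span implantation and the formation of the egg cylinder. Each stage had 1 column, so no single ratio has a replicate error. The spread of the ratios over rows (SD) was 0.50 at E3.5, 0.78 at E4.5, 0.87 at E4.75, 0.74 at E5.5 and 0.83 at E6.0.

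The first question was whether the symbols that the platform annotation gives to the rows are borne out by the values. 1309 symbols had 2 or more rows with values in all columns, which made 2959 rows and 2085 pairs of rows. Over these pairs the correlation of log2 ratios was -0.03 at E3.5, 0.01 at E4.5, 0.01 at E4.75, -0.01 at E5.5 and -0.02 at E6.0. Shuffled names gave -0.04 to 0.04 in the central 95% at each stage, and the permutation p over the 5 columns ran from 0.218 to 0.669 (adjusted p 0.669 in each). The same 2959 rows correlated at 0.87 between E5.5 and E6.0 and at 0.76 between E4.5 and E4.75. These correlations are across rows, which are not independent replicates. Where a row was at least 4-fold higher at E6.0, the other rows of its symbol averaged -0.04 and 48.4% of them lay above 0. Where a row was at least 4-fold lower at E6.0, the other rows of its symbol averaged 0.13.

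**Figure D1:**
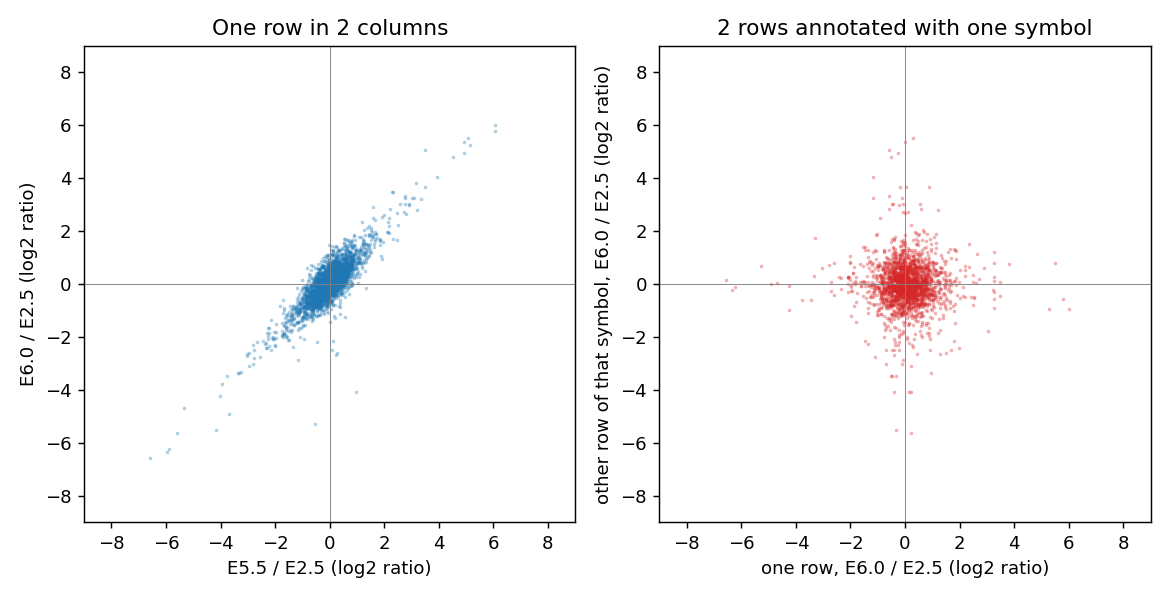
Left, the log2 ratio of each of 2959 rows at E5.5 (x axis) and at E6.0 (y axis); right, the E6.0 log2 ratios of the 2085 pairs of rows that the annotation gives to one symbol, one row on each axis. Points on the left follow the diagonal (r = 0.87), while points on the right show no relation (r = -0.02).

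Of the 6 key genes with several rows, all but Sparc had rows on both sides of 0 at E6.0, some of them close to 0. The rows annotated Lrp2, the endocytic receptor megalin, read 0.86 and -1.67 at E6.0 and lay on opposite sides of 0 in all 5 columns. The rows annotated Dab2, an adaptor of that receptor, read -0.28 and 0.46 at E6.0, -0.32 and -0.33 at E5.5, and 0.71 and -0.48 at E4.75. Those annotated Col4a1, a basement membrane collagen, read -0.28 and 0.12 at E6.0, -0.22 and -0.27 at E3.5, and 0.40 and -1.66 at E4.75. The rows annotated Gata6 read 0.22 and -0.02 at E6.0, and both were above 0 at E4.5, E4.75 and E5.5. Of the 4 rows annotated H19, 1 stood at 0.62 and the others at -0.32, -0.40 and -0.64. The rows annotated Sparc read 1.13 and 0.78 at E6.0, and both were above 0 in all 5 columns. Because the pairs as a whole did not correlate, a symbol below is the annotation's name for a row, and no value is given as an established measurement of that gene.

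Each stage was then compared with E2.5, which asks how far the embryo's transcripts had moved from the cleavage stage. At E3.5, 184 of 6407 symbols were at least 2-fold higher and 103 at least 2-fold lower. At E4.5 the counts were 257 higher and 570 lower, at E4.75 505 and 543, at E5.5 280 and 348, and at E6.0 422 and 403. With columns scaled to one spread, more symbols passed at E3.5 and fewer were higher at E4.75. The counts thus depend on the spread of each column. Over all 15217 rows, named or not, the counts were 510 higher and 264 lower at E3.5, 707 and 1409 at E4.5, 1352 and 1372 at E4.75, 746 and 899 at E5.5, and 1115 and 1038 at E6.0. These row counts do not depend on any name. In all 5 columns at once, 80 rows were at least 2-fold higher and 65 at least 2-fold lower. All columns are relative to E2.5, so a shared reference measurement could put a row past 2-fold in each of them. No count with no change was computed for these rows.

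**Figure D2:**
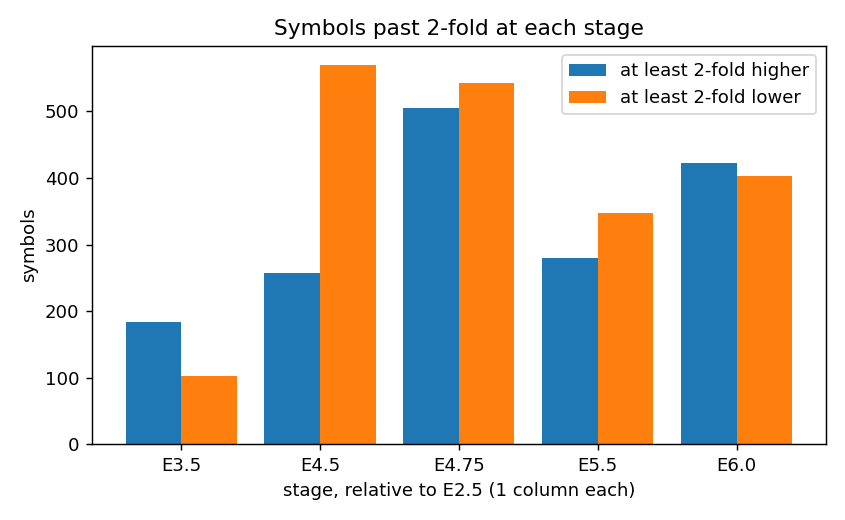
Number of symbols at least 2-fold higher or lower than E2.5 (y axis) at each stage (x axis), out of 6407, with 1 column per stage and therefore no error bars. The lower symbols outnumber the higher ones most at E4.5 (570 against 257).

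The ranks that follow are of symbol averages, in which a symbol with several rows is drawn towards 0. At E3.5 the highest symbols were Hspa14 (log2 ratio 2.90), Cables2 (2.82), Daxx (2.73), Gnptab (2.61) and Pabpc4 (2.46), and the lowest Rab32 (-4.37), Gng12 (-3.45), Timm22 (-3.39), Mmp2 (-3.27) and Rcn3 (-3.23). At E4.5 the highest were Gata4 (4.33), Pgk1 (4.03), Taldo1 (4.02), Cables2 (3.75) and 2510002D24Rik (3.68). The row annotated Gata4 read 0.31 at E4.75, the next stage. The lowest at E4.5 were Abcb8 (-7.67), Cfl1 (-6.38), Bcs1l (-6.18), Arl3 (-6.03) and Efl1 (-5.80). At E4.75 Taldo1 had the highest symbol average, 5.68, followed by Ccdc124 (5.28), Sec24d (4.72), Dppa2 (4.67) and Vcan (4.42). The lowest there were Abcb8 (-9.83), Efl1 (-8.63), Arl3 (-8.29), Bcs1l (-7.52) and Fbp2 (-7.16). Each of these symbols has 1 row, so none could be compared with a second row of its own symbol.

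At E5.5 the highest symbol averages were those of Ccdc124 (5.62), Stx12 (5.52), Vcan (5.45), Wbp4 (5.35) and Lars (5.16), and the lowest Ublcp1 (-4.51), Mamld1 (-4.48), Polr1a (-4.18), Cenpu (-4.16) and Rpl22l1 (-4.09). At E6.0 the highest were Ccdc124 at 5.51, Vcan at 5.38, Snph at 5.35, Stx12 at 5.24 and Wbp4 at 5.17. The lowest symbol averages at E6.0 were Mmp2 (-4.95), Gng12 (-4.78), Cenpu (-4.75), Rpl22l1 (-4.31) and Dcbld1 (-4.24). These symbols also have 1 row each. Single named rows reached further than the symbol averages, from -6.57 to 6.07 at E5.5 and from -6.56 to 6.03 at E6.0. They also did so on 1 side at each earlier stage, with -5.06 at E3.5, -8.13 at E4.5 and 5.80 at E4.75.

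Between consecutive stages, 928 symbols differed at least 2-fold from E3.5 to E4.5, 241 of them higher and 687 lower at the later stage. From E4.5 to E4.75 the number was 432, from E4.75 to E5.5 568, and from E5.5 to E6.0 119. Across the 15217 rows, E5.5 and E6.0 correlated at 0.86 and E4.5 and E4.75 at 0.77, while E3.5 and E4.5 correlated at 0.26, the lowest of the 10 pairs of columns. E3.5 correlated more with E6.0 (0.44) and E4.75 (0.41) than with E4.5 or E5.5 (0.28), so its similarity to the later columns did not follow the order of the stages. The covariances ran from 0.10 (E3.5 and E4.5) to 0.53 (E5.5 and E6.0). All columns are relative to E2.5: in a simulation with no effect and a single shared E2.5 measurement of equal noise, unchanged columns correlated at 0.51, with a covariance of 0.13 at the variance of the E3.5 column. Whether the arrays shared E2.5 pools is not given in the sources used here, and part of each correlation may come from the shared reference.

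A trend over embryonic day was past the threshold for 11 of 6407 symbols, 8 rising and 3 falling (limma, adjusted p under 0.05; 475 had an unadjusted p under 0.05). The rising symbols, each with 1 row, were Snph (slope 2.58 log2 units per day, standard error 0.34, adjusted p 0.037), Zeb1 (2.18), Stx12 (2.17), Vcan (1.94), Nfyb (1.78), Rpusd4 (1.66), and Yif1b and Prdm16, which read 3.56 and 3.55 at E6.0. The falling symbols, also with 1 row each, were Ccdc115 (slope -2.07, standard error 0.17, adjusted p 0.0086), Erc1 (-1.51) and Golga2 (-1.19). The row annotated Ccdc115 went from 2.44 at E3.5 to -2.46 at E6.0. The count changed when a stage was left out: without E4.5 or without E4.75 no symbol passed (534 and 502 at an unadjusted p under 0.05). Without E5.5 1 passed (257 at an unadjusted p under 0.05), without E6.0 4 passed (382), and without E3.5 77 rose and 19 fell (1232). Leaving out a stage also lowers the residual degrees of freedom, so the losses without E4.5 or E4.75 do not show that the calls rested on that stage. All fits with 1 stage left out have the same residual degrees of freedom, yet their unadjusted counts ran from 257 to 1232. The number of calls thus depended on which stage was left out.

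The gene lists, which cover lineages of the early embryo, metabolism, cell cycle, maternal tissue and handling, did not stand apart. None of the 23 lists passed on the trend with limma's camera (smallest adjusted p 0.940, or 0.958 with an estimated correlation), and the smallest unadjusted p was 0.380, for post-implantation epiblast and gastrulation genes. Of 115 list medians over the 5 stages, 2 lay outside the central 95% of random lists, where 5.75 would by chance. Both belonged to the list of epithelium, junctions and blastocoel genes (19 measured members), with a median of -0.19 at E3.5 (percentile 2.11) and -0.33 at E5.5 (percentile 1.52). At E6.0 the 13 members of the visceral endoderm list had a median of -0.16 (percentile 19.0), with 3 at least 2-fold higher and 1 lower. The 23 trophectoderm members had a median of 0.12 (percentile 79.6) and the 18 naive pluripotency members 0.10 (percentile 71.8). The 36 members of the oocyte and early cleavage list had a median of -0.11 (percentile 11.7). Over its members alone, the proteasome list had 2 symbols past an adjusted p of 0.05 (adjusted over the list alone) and 0 over all symbols tested. These medians describe the annotation's names and carry the limit given for them above.

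A check of direction had been set on genes of known course. Of 10 plasma protein genes, 3 were measured, with a median of -0.44 at E5.5 and -0.16 at E6.0; at E4.5 1 was at least 2-fold higher and 1 at least 2-fold lower, and at E6.0 1 was at least 2-fold higher. Of 7 zona pellucida and oocyte genes, 6 were measured, with medians of -0.13 at E3.5, -0.15 at E4.5, -0.20 at E4.75, -0.10 at E5.5 and 0.07 at E6.0. At E4.5 and at E4.75, 1 of them was at least 2-fold lower. With so few genes and names that are not borne out, the check does not settle the direction, which rests on the sample titles; with the ratios turned, higher and lower would swap in every count, rank and trend.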

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

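The setting of rows in place of symbols was chosen after the data had been seen; the others were fixed before the data were examined. Counts for symbols follow the order E3.5, E4.5, E4.75, E5.5, E6.0. With a 3-fold threshold, which takes fewer symbols by construction, 35, 69, 148, 104 and 134 symbols were higher and 26, 203, 184, 114 and 142 lower, and the steps between stages counted 293, 69, 139 and 28. With only symbols that have 2 or more rows, all on one side of 0, again fewer by construction, 8, 17, 41, 23 and 34 were higher and 4, 41, 36, 24 and 28 lower, and the steps counted 83, 25, 36 and 2. With columns scaled to one spread, 450 were higher and 265 lower at E3.5, 272 were higher at E4.75, and 211 differed from E4.5 to E4.75. Scaling stretches the column of the smallest spread, E3.5 (median absolute deviation over rows 0.26). It shrinks those of the largest, E4.5 (0.41) and E4.75 (0.44), so these shifts follow by construction. With rows in place of symbols, 510, 707, 1352, 746 and 1115 rows were higher and 264, 1409, 1372, 899 and 1038 lower, and the steps counted 2517, 1148, 1512 and 335; more units were counted by construction.

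For the trend, leaving out 1 stage gave 0 to 77 rising and 0 to 19 falling symbols: 77 and 19 without E3.5, 0 and 0 without E4.5, 0 and 0 without E4.75, 0 and 1 without E5.5, 3 and 1 without E6.0. Rising symbols numbered 5 with the rank of the stage, 28 with E5.5 and E6.0 against the earlier stages, 4 with column medians subtracted, 0 with columns scaled to one spread (676 at an unadjusted p under 0.05, limma) and 3 among symbols with 2 or more rows, where 1 fell. An adjusted p under 0.1, which takes more symbols by construction, gave 21 rising and 14 falling, and rows in place of symbols 17 and 18. The cause of the other changes was not tested. Subtracting column medians, the median over rows and symbols with a value in the columns compared kept each of the 14 stage and step counts within 1.5 times. No list passed on the trend in any setting run. No named value at E6.0 changed sign by centring or by the median over rows where it was past 2-fold. Centring could not change such a sign, since the median over symbols at E6.0 was 0.0025. For symbols with 1 or 2 rows, the median over rows equals the mean, so this is no test of those values. Signal over background was not used here, so its limit on these counts is unknown.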

Other observations

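The order of the days was tested as set before the data were examined; all other tests in this part were chosen after the result had been seen.

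Some rows moved together in a way that does not depend on their names. At both E5.5 and E6.0, 33 rows were at least 16-fold higher than E2.5, with a median of 5.12 at E6.0, while 30 of them lay within 2-fold of E2.5 at E3.5. At both E4.5 and E4.75, 23 rows were at least 16-fold lower, with medians of -5.16 and -5.98, and 17 of them were within 2-fold at E3.5 and 7 at E6.0. Both sets were picked by their values in the columns named. Over all rows at E3.5, 3.35% were at least 2-fold higher and 1.73% lower, so most rows lay within 2-fold there. Of 156 rows at least 4-fold higher at E5.5 and 201 at E6.0, 143 were shared, where independent lists would share 2.06; part of this may come from the shared E2.5 reference and from features of each spot. The trend's 11 symbols were set against other assignments of the 5 days to the columns: 1 of 100 assignments, the real one, gave as many. The highest other gave 3, so no other order tried gave as many. The columns are single and correlated, so this does not exclude differences between arrays that happen to follow the days. At an unadjusted p under 0.05, 23 of the 100 gave as many as the real 475, and the highest other gave 955, so chance cannot be excluded for that count.

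Rows of one symbol did not share their log2 ratios. Measurement noise in single spots would not repeat between arrays, except through an E2.5 measurement that arrays share. E5.5 minus E3.5 and E6.0 minus E4.5, compared first, correlated at 0.177 over those rows (Spearman -0.02), which decided nothing. Over all 15 pairs of differences that share no column the correlation ran from -0.28 to 0.541, with 4 above 0.3. It was highest for E5.5 minus E4.5 with E6.0 minus E4.75 (0.467 to 0.607 over resampled symbols, widened for the choice among 15). If E5.5 and E6.0 shared one E2.5 measurement, and E4.5 and E4.75 another, noise alone could give such a correlation. Whether they did is not given in the sources used here, so noise stays open. A fixed bias of each spot cancels in such differences, yet the same-symbol correlation of the mean of E5.5 minus E4.5 and E6.0 minus E4.75 was -0.0138 (-0.07 to 0.04). This argues against a fixed bias only if these differences are more than shared noise. A spot bias that differs between sets of arrays was not tested. Names that do not belong to their rows may account for it and stay open: the same-symbol correlation for the pair compared first was not separable from shuffled names (permutation p = 0.324), but this repeats what the columns themselves showed and is no separate evidence. Blocks of rows that share an identifier prefix in the annotation took 3.58% of the variance at E3.5 and 4.72% at E6.0. Of 1000 rotations of the row order, 2 and 3 took as much, and 52, 16 and 29 did at E4.5, E4.75 and E5.5. The E6.0 values stepped down after row 3011, from a median of 0.28 to -0.05. A block ends at row 3031, while a plate would end at row 3072. The step was located at E6.0 only, in a chosen window of rows and without an interval. It therefore does not separate a block's end from a plate's end. Plates of consecutive rows, which are finer than the blocks, took 5.14% of the variance at E3.5 and 5.94% at E6.0. By the rotations alone, the annotation's order followed the values in part at the scale of blocks, most clearly at E3.5 and E6.0. This does not settle the names of single rows. In 155394 shifts and plate layouts of the row order a pooled agreement score ran from -0.06 to 0.07, with -0.01 as deposited. This score averaged products of paired values over the 5 columns, after clipping and removal of row-number patterns, so it is not the correlation given above. In a separate scan of 801 constant shifts the highest mean was 0.05, at a shift of 9 rows, against -0.01 with no shift (SD over shifts 0.01). Other rearrangements within parts of the table were tried without a count being kept. No layout was found that restored the agreement of same-symbol rows, and no gene was named through one.

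Of 33 rows at least 4-fold lower at E3.5, 48.5% were also 4-fold lower at E4.75 and 51.5% at E6.0 (Wilson 95% interval 35.2 to 67.5), against 12.1% at E4.5 (4.82 to 27.3) and 6.06% at E5.5. The rows of the symbols listed above as lowest at E3.5 are among these 33. The 46 rows at least 4-fold higher at E3.5 did not show this order: 19 were also 4-fold higher at E4.5 (41.3%, 28.3 to 55.7), 23 at E4.75, 12 at E5.5 and 14 at E6.0 (30.4%), and the intervals for E4.5 and E6.0 overlap. A course that follows the stages would put E4.5 nearest to E3.5, and the 51.5% at E6.0 goes the other way for the lowered rows, but each stage has 1 column and the intervals cover only the spread over rows, not between arrays, so this stays open. A group of arrays made together may account for the lowered rows, but the labels used here give no array batches, so the 48.5% at E4.75 leaves this open. A biological course that rises and falls between stages was not tested.

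Log2 ratios followed the row number. A period of 24 rows took 9.09% of the variance at E3.5 and 4.17% at E6.0, the smallest of the 5 columns, where 0.15% would arise with no pattern. No period up to 60 rows that is not a multiple of 6 took more than 2.04% in any column. A period of 6 rows, which a period of 24 contains, alone took 7.35% at E3.5 and 3.48% at E6.0. At E4.75 it took 4.40%, where 24 rows took 9.20%. The pattern at E3.5 and E6.0 was thus in large part one of 6 rows. Plate or printing position is consistent with the 4.17%, though a group of related clones on a plate was not separated from it. No biological explanation was tested.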
